A study of Bos taurus with 14 samples.

How the data were processed

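Polyadenylated RNA was measured by sequencing in 14 samples of bovine endometrium, the lining of the uterus, from the ipsilateral uterine horn at the time point labelled day 7 oestrus, taken here as day 7 of the oestrous cycle. The samples were grouped by the fertility label alone: 7 were labelled high fertility and 7 low fertility. Tissue was washed, freed of connective tissue, snap-frozen and extracted with trizol, and libraries were made with an Illumina TruSeq kit, per the labels' protocols. The labels give each sample a number of its own but do not state that each came from a separate cow, so p-values measure the spread between these samples. They give no batch and no pairing of samples, and replicate numbers below only name samples in the order in which they are listed.

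The authors deposited whole-number read counts per gene, not normalised, in 1 file per sample and in 1 table of the whole series. CASAVA 1.4, STAR, HTSeq 0.3p7 and edgeR, and the genome build UMD3.1, are named per the submitters' processing notes. Their settings, the annotation release and whether counting used strand are not given in the sources used here. Each file holds 15524 genes, and the 217336 cells of the series table were compared with the files per sample, of which 0 differed. Of these cells 575 were 0, or 0.265%, and 9 genes were at 0 in every library, so that nearly all genes listed were detected. Whether genes with low counts were removed before the counts were deposited is not given in the sources used here, so shares of genes refer to the genes listed or tested and not to the whole transcriptome. Reads from overlapping genes, antisense partners or near-identical copies can be split or lost by such counting, and this could not be checked without gene models.

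The files do not pair gene identifiers with names. The reference table given for names, of assembly ARS-UCD2.0, holds 37063 genes and no Ensembl identifiers, so 0 identifiers matched. Genes are therefore given by identifier, and at most 2 that rose and 2 that fell are printed. For the same reason 50 lists of pathway, cell type and RNA quality genes fixed before the data were examined, their set tests and their scores per sample were not run, and checks of GC content and gene length were void because no tested gene had a value.

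Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, library sizes were scaled by the trimmed mean of M values (TMM), and the contrast high minus low fertility was tested with robust quasi-likelihood fits (glmQLFit and glmQLFTest) over all 14 libraries without covariates. The threshold was a two-sided Benjamini-Hochberg adjusted p of 0.05. Standard errors were worked back from the fitted log2 change and the F statistic of its test. Intervals of fold changes are 95% intervals from these standard errors. Expression per sample is given as CPM, the usual count rate relative to the TMM-scaled library total, and log2 CPM was computed with a prior count of 2. Depth, composition, component scores and spread were compared by exact two-sided permutation tests over all 3432 splits of 7 against 7, whose smallest possible p is 0.000583. The share of variation between groups was tested one-sided in the same splits. Distances between samples used the 500 most variable genes, and principal components used all tested genes.

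The test, the threshold, the filter, the gene lists, the naming rule and most of the alternatives were fixed before the data were examined. The naming rule took genes with a symbol, and allowed a gene among the 5 smallest p-values to be given by its identifier. Since no gene had a symbol, only that exception applied. The alternatives covered scaling, filtering, the test (DESeq2 1.42.0, limma 3.58.1 with voom, edgeR's exact test), a surrogate variable from sva 3.50.0, library size as a covariate, the threshold, and leaving out each library in turn. The voom fit gave each library a quality weight, and voom without such weights was not run. Covariates made from smooth muscle and epithelium gene lists were also fixed in advance and were not run. Figures were drawn with matplotlib 3.10.9.

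The gene test was tested on simulated counts for this comparison, drawn for 14929 genes from the means, spread and library sizes of the 14 libraries. Of these genes 14865 passed the low-count filter. It called 3 of 50 genes changed 1.5-fold, 30 of 50 changed 2-fold, 47 of 49 changed 4-fold and 47 of 48 changed 8-fold. Of 133 calls, 6 were unchanged genes, or 4.51%. Each gene was drawn independently of the others, and no library was made to depart from the rest. This rate therefore need not hold for real genes, which vary together. Total counts per library were 20641141 to 23641397. The median coefficient of biological variation between samples of a group was 25.9% and the median standard error of a log2 change 0.188. That error was 0.143 for genes above 100 CPM and 0.350 for genes below 1 CPM. Counting error was not set against the spread between samples.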

Results

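Endometrium of cows labelled high fertility (7 samples) and low fertility (7 samples) was profiled by RNA sequencing on day 7. By this day of the cycle the uterus is under rising progesterone, before attachment of an embryo. Libraries held 20641141 to 23641397 counts over 15524 genes, of which 15438 to 15499 were detected per library. Totals ranged from 22171635 to 23641397 in high and from 20641141 to 23344232 in low fertility samples, and mean depth differed by less than the spread between samples (exact permutation p = 0.481). The 10 most abundant genes took 9.88 ± 1.22% of counts (SD, n = 7) in high and 9.07 ± 1.28% (SD, n = 7) in low fertility samples (exact permutation p = 0.251). No pair of libraries was alike within counting noise: the lowest chi-square per degree of freedom among the 91 pairs was 35.3.

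The study asked which endometrial genes differ between high and low fertility cows. Of 14929 genes tested, 5 passed the threshold, 3 higher and 2 lower in high fertility. ENSBTAG00000022590 and ENSBTAG00000006963 fell by several-fold in high fertility endometrium, while ENSBTAG00000015919, ENSBTAG00000000341 and another gene rose by less than 2-fold. For each gene that rose, all 7 high fertility samples lay above all 7 low fertility samples. The genes that fell were at a low level in all 7 high fertility samples and at a high level in most low fertility samples.

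ENSBTAG00000022590 was expressed at 65.4 ± 17.1 CPM (SD, n = 7) in high fertility and 315 ± 131 CPM (SD, n = 7) in low fertility samples. This was a 4.82-fold lower level by the fitted log2 change of -2.27 (SE 0.306, 95% interval -2.92 to -1.62). Its adjusted p was 0.0188 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Low fertility replicate 6, at 76.6 CPM, lay within the high fertility range of 45.3 to 85.6 CPM, so 5 of the 7 high fertility samples lay below all low fertility samples.

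ENSBTAG00000006963 was expressed at 2.86 ± 0.402 CPM (SD, n = 7) in high fertility and 43.1 ± 28.0 CPM (SD, n = 7) in low fertility samples, 15.1-fold lower by the fitted log2 change of -3.91 (SE 0.588, 95% interval -5.16 to -2.66). The adjusted p by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0324. By limma-voom with a quality weight for each library the log2 change was smaller, -2.89, with an adjusted p of 0.123. Across all fits the adjusted p reached 0.127. High fertility samples ranged from 1.98 to 3.15 CPM. Low fertility replicates 3 and 5 lay just above that range, the lower of them at 3.16 CPM, and the other 5 reached up to 71.0 CPM. The gene thus had separate levels within the low fertility group, which its mean there does not show.

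ENSBTAG00000015919 rose from 66.3 ± 6.65 CPM (SD, n = 7) in low to 114 ± 16.9 CPM (SD, n = 7) in high fertility samples, a 1.72-fold higher level (log2 change 0.78, SE 0.108, 95% interval 0.55 to 1.01). Low fertility samples reached at most 71.8 CPM and high fertility samples began at 88.8 CPM. Its adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0188. ENSBTAG00000000341 rose from 78.9 ± 7.15 CPM (SD, n = 7) to 121 ± 14.4 CPM (SD, n = 7), 1.53-fold (log2 change 0.61, SE 0.0955, 95% interval 0.41 to 0.81), with an adjusted p of 0.0383 by the same edgeR test with Benjamini-Hochberg adjustment. The third gene that rose went from 39.9 ± 5.66 CPM (SD, n = 7) to 65.7 ± 8.52 CPM (SD, n = 7), 1.64-fold (log2 change 0.72, SE 0.115). Its adjusted p was 0.0400 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

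**Figure D1:**
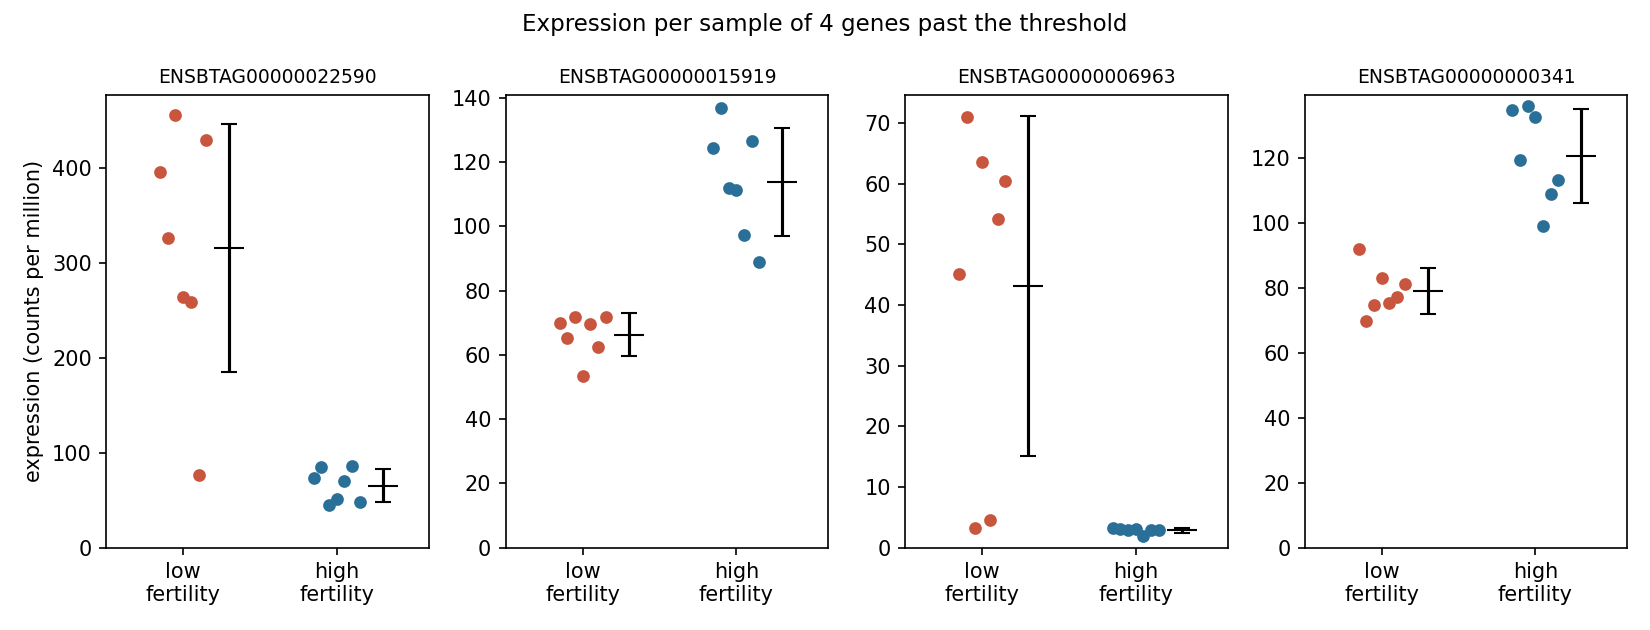
Expression in CPM (vertical axes, starting at 0) of ENSBTAG00000022590, ENSBTAG00000015919, ENSBTAG00000006963 and ENSBTAG00000000341 in each low and high fertility sample (points, 7 per group), with the group mean and SD (black bars). The groups do not overlap for ENSBTAG00000015919 and ENSBTAG00000000341, while low fertility replicate 6 lies at the high fertility level of ENSBTAG00000022590, at 76.6 CPM.

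The count of calls was 1 to 19 across other scalings, tests and covariates and 0 to 5 without 1 library. The direction of the 5 genes was the same in every fit, but the fits share most libraries, so this is no separate support. By edgeR's quasi-likelihood test 0 genes passed without low fertility replicate 2 or 4, or without high fertility replicate 2, 3, 4 or 6, where 748 to 1231 genes had an unadjusted p under 0.05. Of the 14 fits without 1 library, ENSBTAG00000022590 passed in 7, ENSBTAG00000006963 in 3, ENSBTAG00000015919 in 8, and ENSBTAG00000000341 and the third gene that rose in 2 each.

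For most of the genes tested a difference of 2-fold or more was excluded, while smaller differences stay open. The 95% interval of the fold change excluded a 2-fold difference in either direction for 12274 genes, 82.2% of those tested. That share was 93.4% of the 2150 genes above 100 CPM, 90.6% of the 8139 genes between 10 and 100 CPM, 64.9% of the 4071 genes between 1 and 10 CPM, and 44.5% of the 569 genes below 1 CPM. ENSBTAG00000000341 and the third gene that rose, which passed the threshold at 1.53-fold and 1.64-fold, are among the 12274 genes. In the simulated counts the test called only 3 of 50 genes changed 1.5-fold. The median absolute log2 change was 0.149. A fitted change of 2-fold or more was found for 162 genes, 84 higher and 78 lower in high fertility, of which 2 passed the threshold.

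An unadjusted p under 0.05 was found for 1011 genes, 650 higher and 361 lower in high fertility, against 746 by chance. Genes vary together, so this excess is a description and was not tested. Its size varied with the library left out. Without low fertility replicate 3 or 5 the count was 732, below the number chance gives. It was 1825 without low fertility replicate 7 and 1607 without high fertility replicate 1. Without any other single library it was 748 to 1231. With all 14 libraries the count was 3085 by limma-voom with a quality weight for each library. The groups did not overlap for 18 genes, 11 higher and 7 lower in high fertility, where chance gives 8.70, or 0.0583% of genes. With the adjusted p threshold at 0.10, 6 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The sixth had an adjusted p of 0.0634.

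**Figure D2:**
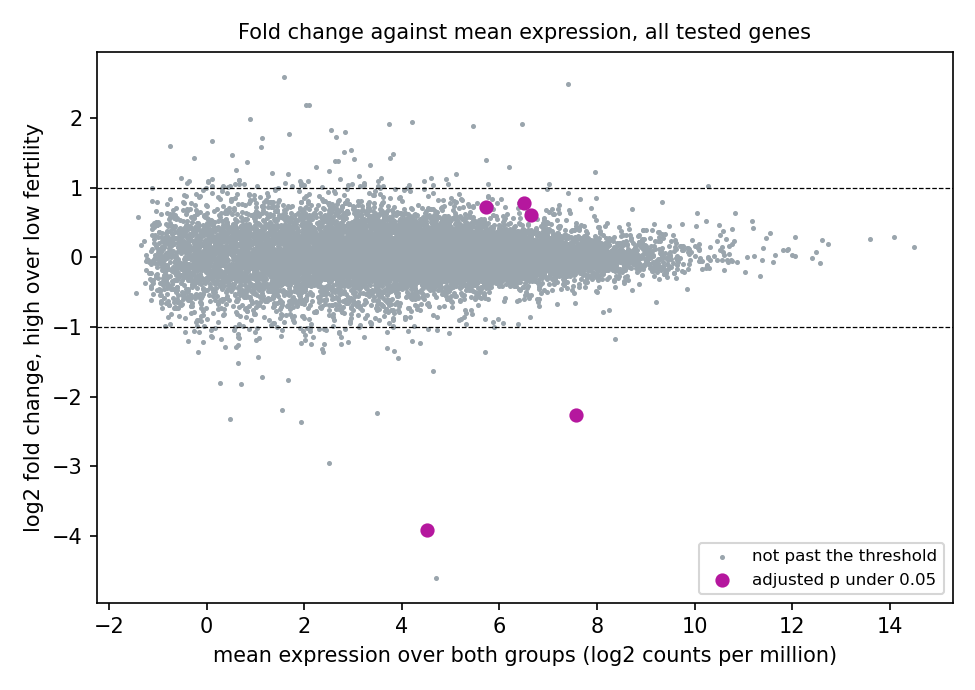
Log2 fold change of high over low fertility (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 14929 genes tested, with the 5 past an adjusted p of 0.05 as large points and dashed lines at 2-fold. Most of the 162 genes beyond the dashed lines are not past the threshold.

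The samples as wholes were not parted by fertility. The median Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.958 for pairs within a group and 0.956 for pairs across groups, with a range of 0.893 to 0.980. The share of squared distance between samples that lay between the groups was 6.77%, and the median of all splits of the samples was 6.76% (exact permutation p = 0.497). The first 5 principal components held 28.3%, 18.0%, 11.7%, 10.4% and 6.69% of the variance. The fourth differed most between groups (exact permutation p = 0.0385), which did not hold after Benjamini-Hochberg adjustment over the 5 components (adjusted exact permutation p = 0.192). Over the 500 most variable genes the mean distance of a sample to its group centre was 29.5 ± 4.63 log2 units (SD, n = 7) in high and 32.1 ± 8.52 (SD, n = 7) in low fertility, a difference of -2.65 that lay within the spread between samples (exact permutation p = 0.624). Over all tested genes the difference was -10.1 (exact permutation p = 0.242).

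**Figure D3:**
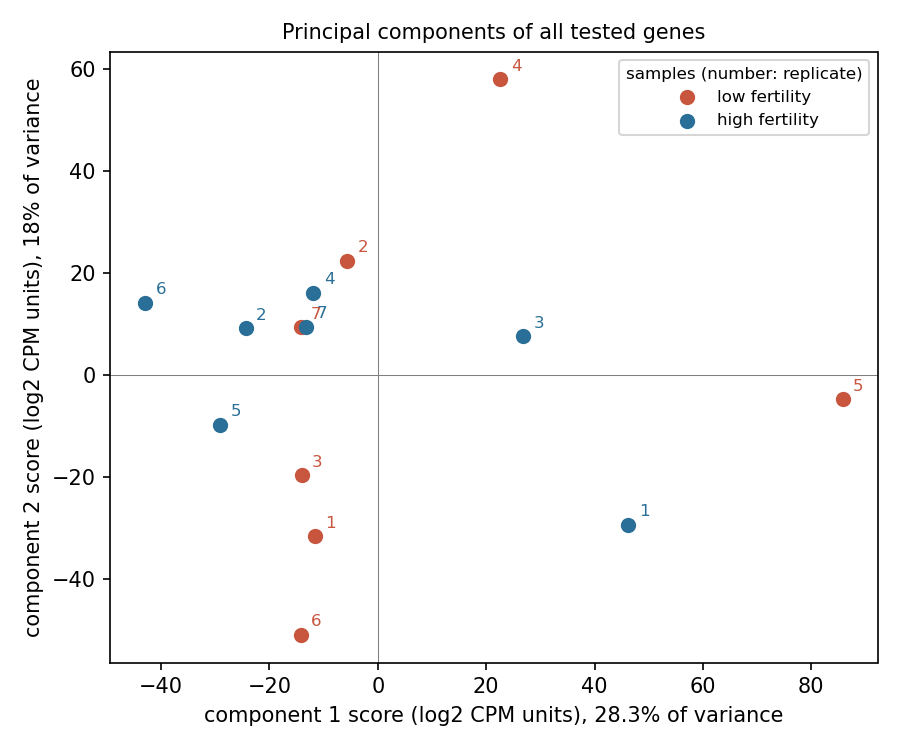
Scores of the 14 samples on principal components 1 (horizontal axis) and 2 (vertical axis), in log2 CPM units, coloured by fertility group and numbered by replicate. The groups overlap on both axes, which hold 28.3% and 18.0% of the variance, and low fertility replicate 5 lies at 85.8 on component 1.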

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

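All tests of the parting of samples along component 2, the test of rare transcripts in the pair that departs together, the test for swapped samples, the search for genes that follow the called genes, the depth test of that pair, and the shuffled profiles were chosen after the result was seen. In 5 of 32 groups of 7 values a sample lay far from the others of its group, where chance gives about 1 in 20. Low fertility replicate 6 had the fewest counts, 20641141, against 22334326 for the next of its group. Low fertility replicate 5 lay at 85.8 on component 1, against 22.6 for the next. It also had 416 genes set apart from the other 13 samples, against 157 for replicate 4, the next. High fertility replicate 5 lay at 27.4 on component 5 and had the lowest level of ENSBTAG00000006963, 1.98 CPM against 2.86 CPM for the next of its group.

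The number of genes past the threshold was set against other splits of the 14 samples into 7 and 7. Of 100 splits, 4 gave as many as the 5 genes of the fertility split, itself included, a share of 4%. The exact binomial 95% interval of this share was 1.10 to 9.93%. It is approximate, as it counts the fertility split as a draw, though only the 99 other splits were drawn, of 1716 in all. The interval holds 5%, so chance cannot be firmly excluded. Of the 99 other splits, 93 gave 0 genes, and the highest gave 3741, which points to a structure of the samples that is stronger than that by fertility.

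That split put low fertility replicates 1, 3, 5 and 6 and high fertility replicates 1, 3 and 5 against the rest, the same parting as the lower against the upper 7 scores on component 2. That split cuts a run of scores from -51.0 to 58.0 without a clear gap, between high fertility replicate 3 at 7.64 and high fertility replicate 2 at 9.15. It does not follow fertility, with at most 4 samples of 1 fertility group among 7, and depth is argued against as the whole cause, since 68.5% of its genes still passed with log2 library size as a covariate. Of its 3741 genes 1848 were higher and 1893 lower on the upper side, and 6.09% changed by 2-fold or more. The share of counts in the 10 most abundant genes, 8.88 ± 1.4% on the lower and 10.1 ± 0.851% on the upper side (SD, n = 7 each, exact permutation p = 0.0763), stays open, as 17.9% of the genes passed with it as a covariate, and so do a batch of sampling or library preparation and the state or cell content of the tissue, which cannot be told apart because the labels give neither. With this parting as a block in the same edgeR quasi-likelihood fit, 6 genes passed for fertility, the 5 among them, while within the sides 0 passed on the lower (1197 at an unadjusted p under 0.05) and 1 on the upper (898), with 3 samples of 1 group and 4 of the other in each.

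Among the pair of genes that fell in high fertility, ENSBTAG00000006963 had separate levels within the low fertility group, and ENSBTAG00000022590 had 1 low fertility sample, replicate 6, at the high fertility level. To look for a swap, low fertility samples at the high fertility level of 1 gene were placed at the other genes that passed without them. These samples were nearer high fertility in 1 of 9 placements, or 11.1%. That was 0 of 2 for replicate 3, 0 of 3 for replicate 5 and 1 of 4 for replicate 6. Most of these genes also passed with the sample in its group, so these few placements argue only weakly against a swap. Cells of another type stay open, as no cell type list was run. The highest r of another gene was 0.797 for ENSBTAG00000022590 and 0.785 for ENSBTAG00000006963, so 0 passed 0.9, a bound without a reference value. Genes with r below -0.7 numbered 55 and 8. For ENSBTAG00000022590 the steepest opposed change among genes with r below -0.7 was -0.293 CPM per CPM. This argues only against reads exchanged with 1 of those genes. A partner with a weaker r, or several partners sharing the reads, would have been missed and stay open. Exchanged reads also stay open for ENSBTAG00000006963, where the steepest opposed change was -0.939 CPM per CPM. There 3 genes passed the bound of 0.5 set in advance. Of 1000 shuffled profiles of that gene, 31.8% had at least 3 genes past the same bound. For either gene, reads exchanged with genes outside those tested could not be checked. A genetic variant between animals, at the gene or at its reads' match to the reference, was not tested and stays open, as does fertility itself.

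Low fertility replicates 4 and 5 departed together from the other 12 samples by at least 2-fold at 68 genes, 4 above and 64 below. Only 1 of 91 pairs, this one, had as many, and the next had 18. The pair was picked from these same data, so its rank is a description and not a test. Total depth is argued against as the cause, with 0 of the pair outside the range of the other 12. So is a few genes taking most of the counts. The 10 most abundant genes took 9.60% in replicate 4, within the range of 8.40 to 11.4% in the other 12. In replicate 5 they took 6.57%, the lowest share of all 14. The pair had the fewest genes detected, 15467 and 15438 against 15478 to 15499 in the other 12. Without the 68 genes it still had the fewest, 15401 and 15373 against 15410 to 15431. Of the 64 genes, 4.69% had a median under 20 counts in the other 12. The median over these genes was 304 counts, so most of them were not rare. Only 569 of the 14929 genes tested lay below 1 CPM, so a low share was likely in any case. A loss of rare transcripts elsewhere in these libraries stays open. A sample deposited as a pair of libraries is argued against, as their chi-square per degree of freedom of 206 was 80th from the lowest of 91 pairs, while other differences in RNA or library quality stay open and no biological explanation was tested.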

How the results depend on the processing

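Leaving out low fertility replicates 4 and 5 together and the parting along component 2 as a block were chosen after the data were seen. The 5 genes (3 higher, 2 lower in high fertility) all passed with median-of-ratios factors, no low-count filter, at least 1 CPM in 7 libraries, no robust estimation and the first surrogate variable. Upper quartile factors and no composition factor each gave 3 genes (1 higher, 2 lower), and log2 library size as a covariate 1 (0 higher, 1 lower). DESeq2 gave 19 (13 higher, 6 lower, with all 5 among them) and edgeR's exact test 10 (7 higher, 3 lower, with 4 among them). Limma-voom with quality weights gave 8 (7 higher, 1 lower, with 4 among them). A log2 change of at least 1 left 2 (0 higher, 2 lower), as did leaving out low fertility replicates 4 and 5 (0 higher, 2 lower). Leaving out 1 library gave 0 to 5 genes (0 to 3 higher, 0 to 2 lower): 0 without low fertility replicate 2 or 4 or high fertility replicate 2, 3, 4 or 6, 1 without high fertility replicate 7, and 3 without low fertility replicate 1, 3 or 7 or high fertility replicate 1 or 5. The cause was not tested. In 27 fits, which share most libraries, the log2 change kept its sign for each gene, at -2.44 to -2.16 for ENSBTAG00000022590, -4.12 to -2.89 for ENSBTAG00000006963, 0.72 to 0.83 for ENSBTAG00000015919 and 0.57 to 0.65 for ENSBTAG00000000341. They passed in 20, 14, 19 and 10 of these fits, with adjusted p up to 0.0822, 0.127, 0.0982 and 0.237 by the tool of each fit with Benjamini-Hochberg adjustment. The share of genes whose interval excluded a 2-fold difference was 79.1% to 85.9% in every fit that gave one. The difference in spread between groups was -10.1 over all tested genes (exact permutation p = 0.242) and reversed to 4.63 (exact permutation p = 0.218) without low fertility replicates 4 and 5, and the share lying between groups stayed without support there (9.44%, exact permutation p = 0.336). Gene list tests, list scores and the smooth muscle and epithelium covariates were not run, since no identifier could be paired with a name. The median standard error of the log2 change was largest, 0.350, for the 569 genes below 1 CPM.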

Other observations

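The tests of genes with separate levels were chosen after the result was seen. Across the 14 samples 20 genes had separate low and high levels, with a gap of at least 2 on the log2 scale and at least 2 samples at each level. ENSBTAG00000006963 was the only one of the 5 called genes among them. Only low fertility samples were at the low level of 8 of the 20 genes, and only high fertility samples at that of 2. A hypothesis is that such genes follow the fertility groups. The difference between the groups in samples at the low level, taken without its sign and summed over the 20 genes, was 39, against a median of 22 over all splits, and 4.84% of the 3432 splits had as much. It counts genes of either direction, and ENSBTAG00000006963, at the low level in all 7 high and 2 low fertility samples, adds to it. The sum was the second measure tried, after a count of genes past a Fisher's exact test that most of the 20 genes could not reach, by which 13.3% of splits had as many. Low fertility replicates 4 and 5 alone were at the low level of 6 of the genes, and without these 6 the share of splits was 5.13%, so the hypothesis stays open.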
